A study of Mus musculus with 8 samples.

How the data were processed

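The deposited tables held 1 file per library, 8 in all, from NMuMG cells grown in DMEM with serum and insulin, per the labels. Per the series text, reads were aligned with STAR 2.7.3a to GRCm38.p6 and counted with featureCounts 2.0.0. Per the submitters' processing notes, the authors used DESeq2 1.26.0, and the series text gives it as the source of variance-stabilized values, which were not used here. The series text names an Ensembl release 75 gene model, while the column headers carry the word ucsc and some symbols are newer than that release, so the gene model behind the values is uncertain. The values are TPM, as the deposited column headers state, and summed to 1000000 in each library. Sample labels were followed for the groups: Kusabira Orange vector at day 9 (control), Osr2 vector at day 3, Osr2 vector at day 9, and TGF-β1 for 2 days, with 2 libraries each. The series text describes the control as cells kept for 2 days without TGF-β, which differs from the sample labels. Replicate numbers in the column headers (1 and 3, 1 and 4, 1 and 3, 2 and 3) differ from those in the labels.

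Each file held 25033 genes. Of these, 26 with symbols turned into dates by a spreadsheet were left out (0.0785 to 0.135% of TPM), leaving 25007. Mitochondrially encoded genes were not analysed here. Whole reads were recovered from the TPM values by finding the read step of each library from 209 genes and a gene length shared by all libraries, within a tolerance of 1e-06, and this gave whole numbers for all 17313 genes above 0. Tested on simulated data, 99.7% of 16325 genes were recovered exactly, and the ratio of reads to length in 100%. Libraries held 8358354 to 9722569 recovered reads and 14274 to 14850 genes above 0, and for a gene of 1 kb 3 reads were 0.599 to 0.699 TPM. A group at 0 reads was given a floor of 3 reads per library. Locations came from GENCODE M21.

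Genes with TPM of 1 or more in at least 2 of the 8 libraries, 12343 in all, were compared as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit on 4 group means, contrasts.fit, eBayes with trend), with no covariates. The fit left 4 residual degrees of freedom, and 1 spread per gene was shared by all groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 5 comparisons: each group against the control, Osr2 day 9 against Osr2 day 3, and Osr2 day 9 against TGF-β. Adding 1 to TPM makes fold changes of low genes too small. Errors in the text are SDs of 2 libraries.

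Before the files were opened, 39 gene lists (747 genes) were written from general knowledge, and the 35 with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Each was repeated with an estimated correlation and with fry. Members were also counted with p-values adjusted over the list alone. Shared responses were counted with Fisher's exact test and set beside 100 simulated data sets with no effect and the same controls (seed 1). In simulated data, 200 changed genes were drawn from those at 5 TPM or more in the control. Of these, 68 to 76% of changes of 1 on the log2 scale and 97 to 100% of changes of 2 were called. Per comparison, 7 to 13 unchanged genes and 0 of 34 random lists were called. The simulated genes were independent and had the same spread in all groups. List calls under correlation and gene calls under unequal spreads were therefore not tested.

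Genes named in the text followed a rule fixed before the files were opened: 11 EMT and TGF-β genes against the control (Osr2, Cdh1, Epcam, Cdh2, Fn1, Vim, Snai1, Snai2, Zeb1, Zeb2 and Smad7), the 6 largest rises and 6 largest falls among called genes with a mean TPM of 5 or more in 1 of the groups, no overlap between libraries and no clone name, up to 4 called members of each list (or the 2 with the highest TPM where none was called), and 5 genes called in opposite directions with Osr2 and TGF-β. One more gene that the rule names is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

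Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter of TPM 5 in at least 2 libraries, median-of-ratios scaling, quantile normalization, rescaling without Osr2, the replicate number as a block, a fit of only the 4 libraries compared, eBayes without trend or with robust fitting, a minimum log2 fold change of 1, and leaving out each library in turn. Limma voom on the recovered reads, library weights from limma arrayWeights, and overlaps with each response against its own control library were chosen after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, counting and drawing.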

Results

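RNA sequencing was compared in NMuMG cells, a mouse mammary gland epithelial line in which TGF-β induces epithelial-mesenchymal transition (EMT). The 8 libraries fell into 4 groups of 2. Cells carried a retroviral vector for Osr2, a zinc finger transcription factor of the odd-skipped family, for 3 or 9 days, or a vector for the fluorescent protein Kusabira Orange for 9 days (the control), or were treated with 5 ng per mL TGF-β1 for 2 days. The only control was taken at day 9, so the day 3 and TGF-β groups differed from it in days as well, and the TGF-β group also in the vector. Each library held 8358354 to 9722569 reads recovered from the deposited TPM values. Expression was compared for 12343 genes. No source used here says whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. That spread was pooled per gene over all 4 groups, so it also holds libraries outside the comparison at hand.

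Osr2 (chromosome 15, 35296098 to 35303305, plus strand, GRCm38) had 0 reads in both control libraries and in both TGF-β libraries, where the 3 reads that a count of 0 allows would be at most 0.380 TPM per library. It reached 435 and 132 TPM in the Osr2 day 3 libraries, 283 ± 214 (SD, n = 2), and 175 and 184 TPM at day 9, 179 ± 5.94 (SD, n = 2). Against the floor of 3 reads per control library, Osr2 was at least 746-fold higher at day 3 and at least 472-fold higher at day 9. The labels of the 4 groups therefore matched the presence of the transgene, and the 2 day 3 libraries differed 3.29-fold in its level. Floors and intervals here cover counting error only.

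**Figure D1:**
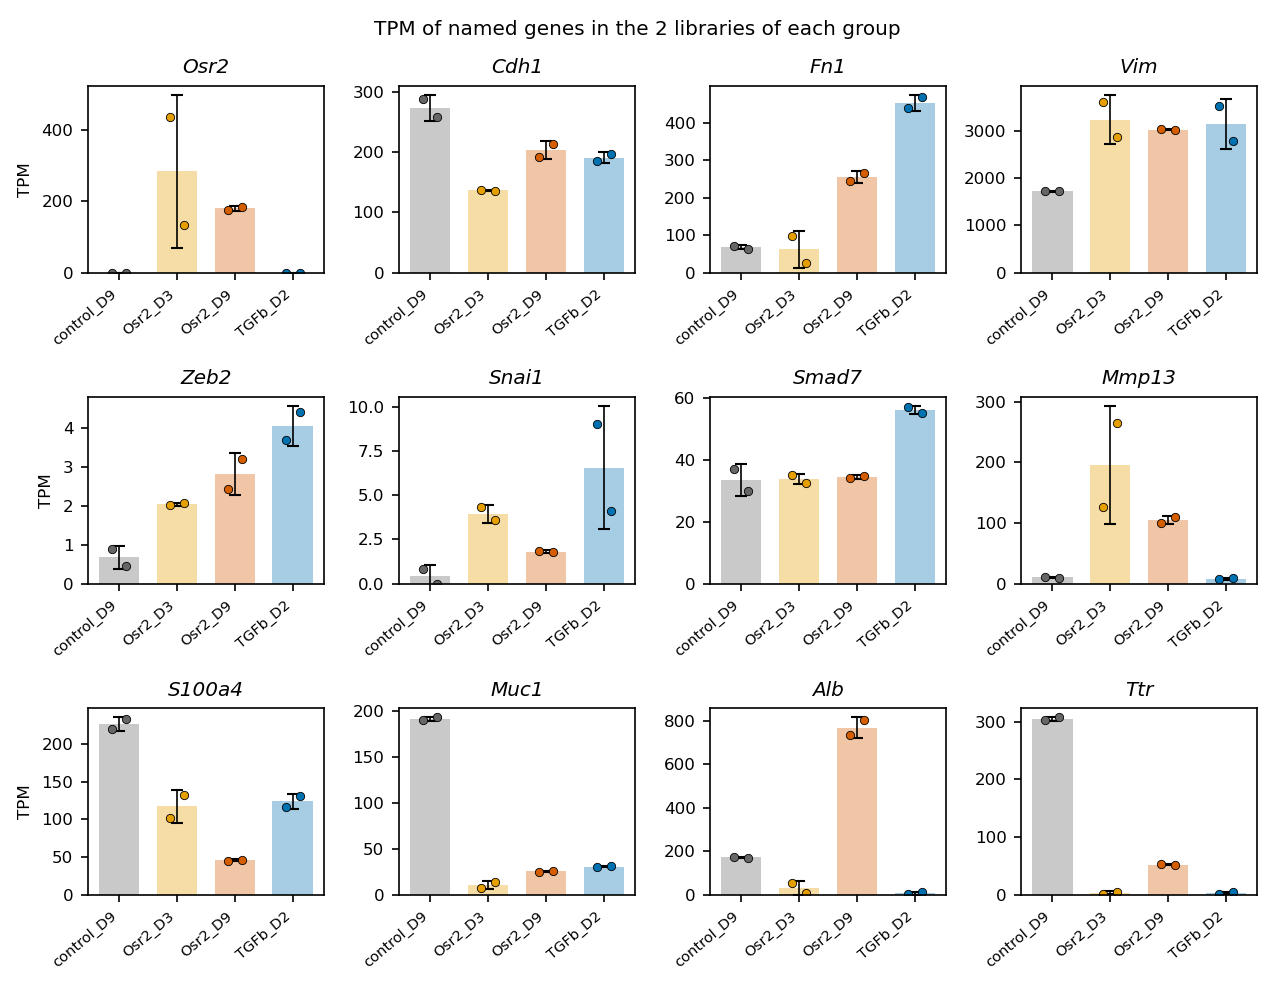
TPM of 12 genes in each group, with bars at the mean of 2 libraries, error bars of 1 SD and a point for each library. Osr2 was absent from the control and TGF-β libraries, Fn1 and Vim were higher at Osr2 day 9 than in the control, and the mean of Snai1 was highest with TGF-β.

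The comparison of Osr2 with the control vector at day 9 asked what Osr2 changed at a matched time. Fibronectin, Fn1, a matrix protein used as a mesenchymal marker, rose from 67.7 ± 5.51 to 256 ± 14.9 TPM (SD, n = 2; log2 fold change 1.90, adjusted p = 0.0494). The p-value of Fn1 rests on the pooled spread, which includes the Osr2 day 3 libraries, where Fn1 differed widely, and not on these SDs alone. Vimentin, Vim, an intermediate filament of mesenchymal cells, rose from 1731 ± 11.7 to 3038 ± 5.53 TPM (adjusted p = 0.0149), and Zeb2, a repressor of E-cadherin, from 0.670 ± 0.296 to 2.81 ± 0.539 TPM (adjusted p = 0.0173). E-cadherin itself, Cdh1, the main adhesion molecule of epithelial junctions, fell from 273 ± 21.3 to 203 ± 15.3 TPM (log2 fold change -0.43, adjusted p = 0.0431). Other EMT genes were not called: the log2 fold changes were Epcam -0.12, Cdh2 0.39, Snai1 1.05, Snai2 0.82 and Zeb1 -0.02, and that of the TGF-β target Smad7 was 0.05.

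In all, 922 genes were called between Osr2 day 9 and the control, 580 higher and 342 lower. Besides Osr2, the largest rises by log2 fold change were in the sodium pump regulator Fxyd3 (4.23, from 2.26 ± 0.504 to 60.1 ± 4.70 TPM), the actin-bundling protein Fscn1 (3.75), the potassium channel subunit Kcne2 (3.59), the uroplakin Upk1b (3.33) and the collagenase Mmp13 (3.25, from 10.1 ± 1.25 to 105 ± 6.603 TPM). The largest falls were in Spp2 (-3.11), the apical mucin Muc1 (-2.88, from 191 ± 2.26 to 25.1 ± 0.249 TPM), the actin-capping protein Capg (-2.79) and Prl2c2 (-3.63), a proliferin whose near-identical copies make its reads uncertain. The small RNAs Mir92b and Snord68 also fell by the test, on 9 and 5 control reads against 0 and 0, and lie in or beside longer transcripts.

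Of the 35 gene lists fixed before the data were examined, camera called 11 higher and 4 lower at Osr2 day 9. Among mesenchymal and EMT markers, of 21 tested, 5 rose, 1 fell and 15 were not called (7 and 1 adjusted over the list alone). For mesenchymal and EMT markers, camera gave adjusted p = 0.00194, and adjusted p = 0.526 with an estimated correlation. Col6a1, a type VI collagen chain, rose from 4.51 ± 1.76 to 34.01 ± 0.280 TPM, while S100a4, a calcium-binding protein also known as fibroblast-specific protein, went the other way, from 227 ± 9.104 to 45.7 ± 1.07 TPM (log2 fold change -2.29). Among fibrillar collagens and matrix proteins, of 25 tested, 8 rose, 0 fell and 17 were not called (9 and 4 adjusted over the list alone), with Col6a2 at 2.07. For matrix proteins, camera gave adjusted p = 0.0222, and adjusted p = 0.526 with an estimated correlation. Among matrix proteases and inhibitors, of 17 tested, 5 rose, 0 fell and 12 were not called (7 and 0 adjusted over the list alone), with Timp3, an inhibitor of metalloproteinases, at 3.12. For proteases, camera gave adjusted p = 0.00311, and adjusted p = 0.446 with an estimated correlation. Among actin cytoskeleton and contractile genes, of 20 tested, 2 rose, 0 fell and 18 were not called (9 and 0 adjusted over the list alone), with Cnn3 at 0.70. For actin genes, camera gave adjusted p = 0.00311, and adjusted p = 0.652 with an estimated correlation. Fibroblast markers, a check for another cell type, moved with these groups: of 6 tested, 3 rose, 1 fell and 2 were not called (3 and 1 adjusted over the list alone), with Clec3b at 2.28, Gsn at 0.83 and Twist2 at -1.27. For fibroblast markers, camera gave adjusted p = 0.0333, and adjusted p = 0.462 with an estimated correlation. Among other cell types with under 5 tested markers, the immune markers Csf1r and Cd14 rose by 0.91 and 0.43, the adipocyte marker Plin4 rose from 0.593 to 8.19 TPM while Pparg was at -1.04, and the endothelial markers Eng, Flt1 and Egfl7 were not called.

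Of the signalling and stress lists, camera called 6 higher at Osr2 day 9, and the Wnt, hedgehog, SMAD target and TGF-β pathway lists were not called. Among BMP and ID target genes, of 11 tested, 4 rose, 0 fell and 7 were not called (5 and 0 adjusted over the list alone), led by Hey1, Atoh8 and Bmp4 (log2 fold changes 2.01, 1.95 and 1.262). For BMP and ID targets, camera gave adjusted p = 0.00916, and adjusted p = 0.526 with an estimated correlation. That call was lost without control replicate 1 (camera adjusted p = 0.0782), as were those of the Notch, NF-kB, interferon and fibroblast lists. Among Notch target genes, of 10 tested, 4 rose, 0 fell and 6 were not called (4 and 0 adjusted over the list alone), with Hey1 again and Notch1 at 1.08. For Notch targets, camera gave adjusted p = 0.0232, and adjusted p = 0.506 with an estimated correlation. Among YAP and TAZ targets, of 20 tested, 1 rose, 1 fell and 18 were not called (7 and 1 adjusted over the list alone), where F3 rose by 0.65 and Fjx1 was at -1.27. For YAP and TAZ targets, camera gave adjusted p = 0.00311, and adjusted p = 0.652 with an estimated correlation. Among p53 targets, of 20 tested, 6 rose, 0 fell and 14 were not called (10 and 0 adjusted over the list alone), with the death receptor Fas at 1.52 and the BH3-only genes Pmaip1 and Bbc3 at 1.23 and 1.13. For p53 targets, camera gave adjusted p = 6.29e-05, and adjusted p = 0.446 with an estimated correlation. Among inflammatory NF-kB genes, of 18 tested, 4 rose, 1 fell and 13 were not called (10 and 1 adjusted over the list alone), with lipocalin, Lcn2, at 3.15. For NF-kB genes, camera gave adjusted p = 0.0167, and adjusted p = 0.652 with an estimated correlation. Among interferon-stimulated genes, of 15 tested, 2 rose, 0 fell and 13 were not called (3 and 0 adjusted over the list alone), with Ddx58 at 0.72. For interferon-stimulated genes, camera gave adjusted p = 0.0244, and adjusted p = 0.446 with an estimated correlation.

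Of the growth and metabolism lists, camera called 4 lower at Osr2 day 9, and the cholesterol, fatty acid and ribosomal protein lists were not called. Among cell cycle genes, of 30 tested, 0 rose, 0 fell and 30 were not called (0 and 0 adjusted over the list alone), with a median log2 fold change of -0.44 and the 2 most abundant members, Pcna and Mcm7, at -0.37 and -0.29. For cell cycle genes, camera gave adjusted p = 5.99e-05, and adjusted p = 0.652 with an estimated correlation. Among nuclear oxidative phosphorylation genes, of 26 tested, 0 rose, 1 fell and 25 were not called (0 and 5 adjusted over the list alone), with the succinate dehydrogenase subunit Sdhd at -0.42. For oxidative phosphorylation, camera gave adjusted p = 6.29e-05, and adjusted p = 0.292 with an estimated correlation. Among glycolysis and hypoxia genes, of 25 tested, 1 rose, 7 fell and 17 were not called (3 and 12 adjusted over the list alone), with Pdk1 and Pgk1 at -0.84 and -0.78 and the collagen hydroxylase P4ha2 at 1.23. For glycolysis and hypoxia, camera gave adjusted p = 0.000158, and adjusted p = 0.526 with an estimated correlation. Among amino acid response ATF4 targets, of 23 tested, 1 rose, 3 fell and 19 were not called (2 and 6 adjusted over the list alone), with Nupr1 at 1.29 and Shmt2 at -0.51. For ATF4 targets, camera gave adjusted p = 0.0218, and adjusted p = 0.652 with an estimated correlation. The TGF-β SMAD target list was not called (camera adjusted p = 0.963), nor were the epithelial junction, EMT transcription factor or luminal mammary lists. Their members that rose and fell, with the counts adjusted over the list alone in brackets, were 2 and 1 of 25 (3 and 2), 1 and 3 of 31 (1 and 3), 3 and 2 of 15 (5 and 3) and 3 and 1 of 7 (3 and 2).

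The number of day 9 calls depended on the libraries in the fit, and a lone library is assumed to vary like the other groups. Without control replicate 1 the comparison called 59 genes, without control replicate 2 25, and without Osr2 day 9 replicate 1 or 2 45 and 45. Of the 922 genes, 21 were called in each of these 4 fits, among them Osr2, Kcne2, Muc1, S100a4, Aqp8 (log2 fold change 3.09), Pltp (2.48) and Emp2 (2.07), the last 3 named after their values were seen, while Fn1, Vim, Zeb2 and Cdh1 were called in 0 of the 4. Their log2 fold changes in these fits were 1.82 to 1.98 for Fn1, 0.80 to 0.82 for Vim, 1.01 to 1.38 for Zeb2 and -0.51 to -0.35 for Cdh1, and a group of 1 library widens the error by construction. The genes called in each of the 4 fits also include the small RNAs Mir92b and Snord68, which rest on few reads. Being kept therefore does not make a gene dependable. A fit of only the 4 libraries compared called 3304 genes, library weights, chosen after the data had been seen, 2804, and fits without an Osr2 day 3 library 1382 and 1385.

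The comparison of Osr2 day 3 with the control asked what the vector changed early, with fewer days in culture. Cdh1 fell from 273 ± 21.3 to 136 ± 0.635 TPM (SD, n = 2; log2 fold change -0.997, adjusted p = 0.000617), and the epithelial adhesion molecule Epcam from 3.53 ± 0.191 to 1.10 ± 0.0421 TPM (adjusted p = 0.0185). Vim rose from 1731 ± 11.7 to 3249 ± 527 TPM (adjusted p = 0.00301). The E-cadherin repressors Snai1, Snai2 and Zeb2 rose by 1.86, 1.17 and 0.87 on the log2 scale. Cdh2, Zeb1 and Smad7, at 0.02, -0.01 and 0.02, were not called, nor was Fn1, whose day 3 libraries stood apart at 97.2 and 26.8 TPM (log2 fold change -0.39).

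Of the 3934 genes called between Osr2 day 3 and the control, 1510 were higher and 2424 lower. After Osr2, the largest rises by log2 fold change were in the water channel Aqp8 (4.59, from 0.663 ± 0.368 to 38.78 ± 7.40 TPM), Mmp13 (4.05, from 10.1 ± 1.25 to 196 ± 97.3 TPM) and the heat shock protein gene Hspa1b (3.74), which shares reads with Hspa1a and stood at 90.4 and 614 TPM in the 2 libraries. The snoRNAs Snord34 and Snord57, which lie inside host genes, were called on 5 and 9 reads against 0 and 0. The largest falls were in the thyroid hormone carrier Ttr (-6.35, from 305 ± 3.47 to 3.06 ± 2.17 TPM), Depp1 (-5.97), Spp2 (-4.49), and 2 members of multigene families with uncertain reads, Serpina1c (-4.53) and Cyp4a12a (-4.28). Pipox, a peroxisomal oxidase, fell to 3 reads from 342.

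Among cell cycle genes at Osr2 day 3, of 30 tested, 11 rose, 0 fell and 19 were not called (21 and 0 adjusted over the list alone), with the cyclins Ccne1 and Ccne2 at 1.58 and 1.257 and the ribonucleotide reductase subunit Rrm2 at 1.13. For cell cycle genes, camera gave adjusted p = 3.44e-07, and adjusted p = 0.716 with an estimated correlation. Among amino acid response ATF4 targets, of 23 tested, 11 rose, 2 fell and 10 were not called (12 and 2 adjusted over the list alone), with the amino acid transporters Slc7a11 and Slc7a5 at 1.88 and 1.41 and the mTOR inhibitor Ddit4 at -1.93. For ATF4 targets, camera gave adjusted p = 0.000115, and adjusted p = 0.643 with an estimated correlation. Among unfolded protein response and ER chaperone genes, of 20 tested, 3 rose, 0 fell and 17 were not called (0 and 0 adjusted over the list alone), with Hyou1 at 1.35. For the unfolded protein response, camera gave adjusted p = 0.00394, and adjusted p = 0.716 with an estimated correlation. That list lost its call without Osr2 day 3 replicate 2 (camera adjusted p = 0.480). Among matrix proteases and inhibitors, of 17 tested, 7 rose, 1 fell and 9 were not called (9 and 4 adjusted over the list alone), with Mmp10 and Timp3 at 2.84 and 2.76. For proteases, camera gave adjusted p = 0.0268, and adjusted p = 0.643 with an estimated correlation. That call was lost with median-of-ratios scaling, quantile normalization, voom, no filter and a filter of TPM 5 (camera adjusted p 0.0526 to 0.0950).

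Among epithelial junction and identity genes at Osr2 day 3, of 31 tested, 2 rose, 16 fell and 13 were not called (3 and 18 adjusted over the list alone), with keratin Krt19 at -2.14, the tight junction genes Ocln and Tjp3 at -2.03 and -1.72 and desmoglein Dsg2 at -1.51. For junction genes, camera gave adjusted p = 0.00655, and adjusted p = 0.643 with an estimated correlation. Among cholesterol biosynthesis genes, of 23 tested, 1 rose, 14 fell and 8 were not called (1 and 18 adjusted over the list alone), with Insig1 and Lss at -1.53 and -1.26. For cholesterol genes, camera gave adjusted p = 0.000449, and adjusted p = 0.716 with an estimated correlation. Among glycolysis and hypoxia genes, of 25 tested, 1 rose, 13 fell and 11 were not called (1 and 13 adjusted over the list alone), with Aldoc, Pdk1 and Bnip3 at -2.81, -2.57 and -2.04. For glycolysis and hypoxia, camera gave adjusted p = 0.0107, and adjusted p = 0.716 with an estimated correlation. The Wnt target list was called higher on 3 and 1 of 10 (4 and 1) members rising and falling, with the count adjusted over the list alone in brackets, and the p53 target list on 9 and 1 of 20 (9 and 1); both had a camera adjusted p of 0.04999 and adjusted p = 0.643 and 0.716 with an estimated correlation. With the replicate number as a block the p53 list had adjusted p = 0.0650. Myc rose by 0.83 and Mdm2 by 0.86, and the p53 target Btg2 was at -2.83.

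Of the 35 tested lists, 26 were not called at Osr2 day 3. Members that rose and fell, adjusted over the list alone in brackets, were 5 and 1 of 21 (5 and 1) for mesenchymal and EMT markers, 6 and 1 of 15 (7 and 1) for EMT transcription factors, 5 and 3 of 25 (5 and 3) for collagens and matrix and 5 and 8 of 25 (5 and 8) for SMAD targets. Counted the same way, they were 1 and 6 of 15 (1 and 6) for interferon-stimulated genes, 3 and 7 of 18 (4 and 7) for immediate early genes, 5 and 3 of 14 (5 and 3) for NRF2 genes and 0 and 4 of 11 (0 and 5) for MHC class I. For development and cell identity they were 3 and 1 of 12 (3 and 1) for skeletal, palate and kidney development factors, 2 and 5 of 11 (2 and 5) for cell cycle inhibitors and 3 and 1 of 8 (3 and 1) for basal mammary markers. The development factor Sox9 was at -2.04, the immediate early gene Egr2 at -2.74 and Fosl1 at 2.40.

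The share of higher genes at Osr2 day 3 depended on scaling: 1510 higher and 2424 lower (38.4% higher) became 2097 and 2248 (48.3%) with median-of-ratios scaling and 2151 and 2073 (50.9%) with quantile normalization, which moved the median of all genes by 0.10. Without control replicate 1 or 2 the comparison called 1633 and 1852 genes, and 1298 of the 3934, including Cdh1, Vim, Aqp8, Mmp13, Ttr and Krt19, were called without any 1 of its 4 libraries.

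The TGF-β comparison served as a reference for EMT in this line. Fn1 rose from 67.7 ± 5.51 to 454 ± 21.2 TPM (SD, n = 2; log2 fold change 2.73, adjusted p = 0.00623). N-cadherin, Cdh2, rose from 41.3 ± 6.06 to 74.4 ± 8.49 TPM and Vim from 1731 ± 11.7 to 3160.2 ± 529 TPM, while Cdh1 fell from 273 ± 21.3 to 190.3 ± 8.66 TPM (adjusted p = 0.0103). The EMT transcription factors Snai1, Snai2, Zeb1 and Zeb2 rose by 2.40, 0.91, 1.37 and 1.60, and the inhibitory SMAD gene Smad7 by 0.74. Epcam, at 0.53, was not called.

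Against the control, which also differed in days and in the vector, 2471 genes were called with TGF-β, 1533 higher and 938 lower. The largest rises by log2 fold change were in the cytokine Il11 (6.03, from 1.09 ± 0.555 to 136 ± 33.4 TPM), cathepsin W, Ctsw (5.36), the anchoring-fibril collagen Col7a1 (4.49) and Lce1g (4.61), whose family shares sequence. The claudin Cldn4 was called on 475 reads against 3, and Mir12181 on 14 against 0. The largest falls were in Ttr (-6.37), albumin, Alb (-5.02, from 171 ± 2.82 to 6.06 ± 6.57 TPM), Cyp4a12a (-4.64), Depp1 (-4.43), angiotensinogen, Agt (-4.22), and the trefoil peptide Tff3 (-4.11). Ttr, Cyp4a12a and Depp1 were also among the largest falls at Osr2 day 3, without added TGF-β.

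With TGF-β, camera called 12 lists higher and 12 lower. Among fibrillar collagens and matrix proteins, of 25 tested, 15 rose, 1 fell and 9 were not called (17 and 1 adjusted over the list alone), with Thbs1 and Col5a3 at 3.80 and 3.49. For matrix proteins, camera gave adjusted p = 6.04e-07, and adjusted p = 0.258 with an estimated correlation. Among mesenchymal and EMT markers, of 21 tested, 16 rose, 1 fell and 4 were not called (17 and 1 adjusted over the list alone), with Itga5, the fibronectin receptor subunit, at 2.86. For mesenchymal and EMT markers, camera gave adjusted p = 1.24e-06, and adjusted p = 0.258 with an estimated correlation. Among actin cytoskeleton genes, of 20 tested, 15 rose, 0 fell and 5 were not called (15 and 0 adjusted over the list alone), with Zyx and Actn1 at 2.06 and 1.83. For actin genes, camera gave adjusted p = 5.99e-07, and adjusted p = 0.309 with an estimated correlation. Among SMAD targets, of 25 tested, 18 rose, 1 fell and 6 were not called (20 and 2 adjusted over the list alone), with Ltbp1 and Pmepa1 at 2.41 and 2.01. For SMAD targets, camera gave adjusted p = 1.10e-05, and adjusted p = 0.258 with an estimated correlation. Among EMT transcription factors, of 15 tested, 7 rose, 0 fell and 8 were not called (9 and 0 adjusted over the list alone), with Hmga2 at 1.69. For EMT transcription factors, camera gave adjusted p = 0.00302, and adjusted p = 0.258 with an estimated correlation. Among TGF-β pathway ligands, receptors and SMADs, of 20 tested, 8 rose, 0 fell and 12 were not called (10 and 1 adjusted over the list alone), with Inhba and Tgfb1 at 1.84 and 1.43. For pathway members, camera gave adjusted p = 0.00346, and adjusted p = 0.402 with an estimated correlation. Among matrix proteases and inhibitors, of 17 tested, 9 rose, 0 fell and 8 were not called (9 and 0 adjusted over the list alone), with Timp3 and Adam12 at 3.75 and 2.06. For proteases, camera gave adjusted p = 0.000768, and adjusted p = 0.258 with an estimated correlation. Among integrins, of 12 tested, 7 rose, 1 fell and 4 were not called (8 and 2 adjusted over the list alone), with Itgb3 at 1.63. For integrins, camera gave adjusted p = 0.0132, and adjusted p = 0.402 with an estimated correlation. Fibroblast markers were not called as a list, and members that rose and fell, adjusted over the list alone in brackets, were 2 and 0 of 6 (2 and 0), with Col1a1 at 2.53.

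Lower lists with TGF-β included epithelial and BMP genes. Among epithelial junction genes, of 31 tested, 4 rose, 11 fell and 16 were not called (5 and 13 adjusted over the list alone), with Krt19 and Tjp3 at -1.90 and -1.72. For junction genes, camera gave adjusted p = 0.00196, and adjusted p = 0.258 with an estimated correlation. Among epithelial transcription factors and splicing regulators, of 12 tested, 0 rose, 6 fell and 6 were not called (0 and 6 adjusted over the list alone), with Cebpa and Ehf at -1.51 and -1.10. For epithelial transcription factors, camera gave adjusted p = 0.000270, and adjusted p = 0.264 with an estimated correlation. Among BMP and ID targets, of 11 tested, 1 rose, 5 fell and 5 were not called (1 and 5 adjusted over the list alone), with Id1, Id2 and Id3, inhibitors of basic helix-loop-helix factors, at -1.74, -1.61 and -2.24. For BMP and ID targets, camera gave adjusted p = 0.000678, and adjusted p = 0.264 with an estimated correlation. Among NRF2 antioxidant genes, of 14 tested, 1 rose, 4 fell and 9 were not called (2 and 5 adjusted over the list alone), with Gsta4 and Gclc at -3.64 and -1.86. For NRF2 genes, camera gave adjusted p = 0.0144, and adjusted p = 0.402 with an estimated correlation. Among immediate early genes, of 18 tested, 3 rose, 7 fell and 8 were not called (4 and 8 adjusted over the list alone), with Fos and Egr1 at -3.42 and -2.60. For immediate early genes, camera gave adjusted p = 0.00457, and adjusted p = 0.402 with an estimated correlation.

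Of the other lists called with TGF-β, 4 were higher and 7 lower. Members that rose and fell, adjusted over the list alone in brackets, were 6 and 0 of 20 (9 and 1) for YAP and TAZ targets, 5 and 1 of 10 (6 and 1) for Wnt targets, 10 and 1 of 18 (10 and 1) for inflammatory NF-kB genes and 2 and 0 of 30 (1 and 0) for cell cycle genes, which were the 4 higher lists. Their camera adjusted p values were 0.00982, 0.0202, 0.0259 and 0.0121, and adjusted p = 0.502, 0.303, 0.535 and 0.702 with an estimated correlation. The lower lists had 0 and 9 of 32 (0 and 15) for ribosomal proteins, 0 and 7 of 26 (0 and 12) for oxidative phosphorylation, 0 and 9 of 23 (1 and 11) for cholesterol biosynthesis and 4 and 11 of 25 (4 and 12) for glycolysis and hypoxia. They also had 0 and 2 of 13 (0 and 3) for replication-dependent histones, 2 and 4 of 23 (2 and 4) for ATF4 targets and 0 and 3 of 14 (0 and 4) for fatty acid synthesis. Their camera adjusted p values were 1.53e-06, 1.57e-05, 6.91e-05, 0.000602, 0.00196, 0.00457 and 0.0293, and adjusted p = 0.402, 0.258, 0.402, 0.402, 0.402, 0.402 and 0.535 with an estimated correlation. Ribosomal protein genes have many pseudogene copies and are uncertain. Without TGF-β replicate 1 the cell cycle list had adjusted p = 0.955. The hedgehog list was not called, with 1 and 0 of 5 (3 and 0) members counted the same way.

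With median-of-ratios scaling the TGF-β split of 1533 higher and 938 lower (62.0% higher) became 1121 and 1344 (45.5%) and the median of all genes moved by -0.12, and with quantile normalization the split was 1223 and 1285 (48.8%), with a shift of -0.10. Without control replicate 1 or 2 or TGF-β replicate 1 the comparison called 1051, 754 and 1274 genes, and 627 of the 2471 were called without any 1 of its 4 libraries, including Vim, Snai1, Zeb1 and Zeb2 but not Fn1, Cdh1 or Cdh2.

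**Figure D2:**
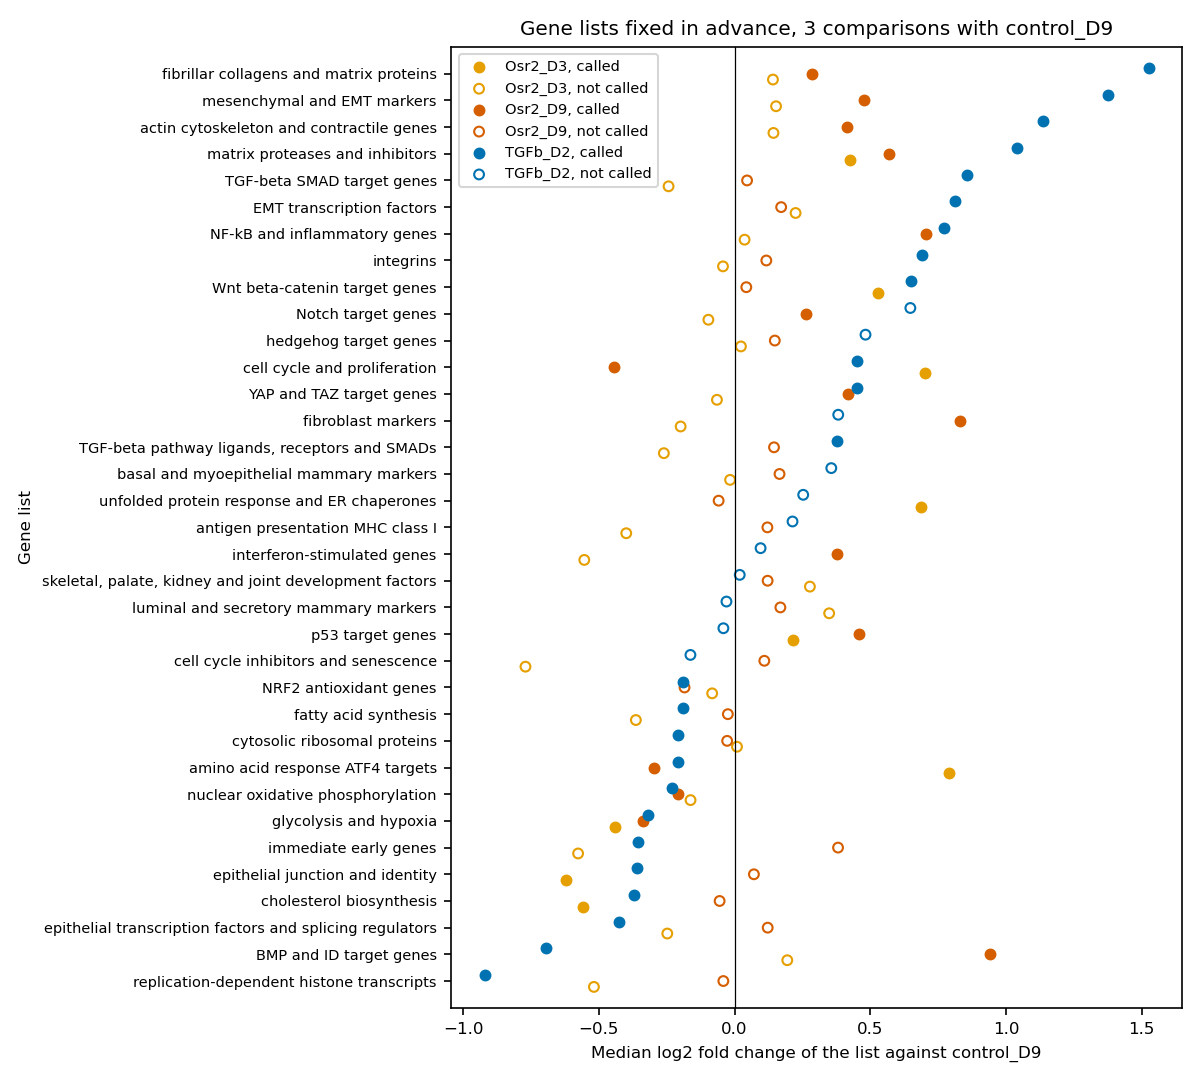
Median log2 fold change of each of the 35 tested gene lists against the control, in Osr2 day 3, Osr2 day 9 and TGF-β libraries, with filled points for lists called by camera with its preset correlation of 0.01. Collagen, mesenchymal and actin lists stood highest with TGF-β. No list kept its call with an estimated correlation.

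Osr2 day 9 was compared with Osr2 day 3 directly, a comparison in which the control libraries cancel and days in culture are not separated. The plasma protein gene Alb rose from 29.8 ± 31.7 to 768 ± 49.3 TPM (SD, n = 2; log2 fold change 5.18, adjusted p = 0.00315), and the acute-phase protein Saa3 from 1.57 ± 0.982 to 98.7 ± 7.98 TPM. Pdzk1ip1, a membrane-associated protein, rose by 6.52, Depp1 by 5.11, and the family members Sult1a1, a sulfotransferase, and Cyp4a12a by 5.68 and 5.38. The largest falls were in Prl2c2 (-6.48), the immune receptor gene Tigit (-4.16), the cornified envelope gene Sprr2h (-4.13), Hspa1b (-3.60) and S100a7a (-3.40). Snord34 had 0 reads at day 9 against 5.

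Of 5345 genes called between the 2 Osr2 times, 3460 were higher at day 9 and 1885 lower. Among cell cycle genes, of 30 tested, 0 rose, 28 fell and 2 were not called (0 and 30 adjusted over the list alone), with Ccne1 and Aurka at -1.83 and -1.44. For cell cycle genes, camera gave adjusted p = 4.64e-12, and adjusted p = 0.709 with an estimated correlation. Among ATF4 targets, of 23 tested, 2 rose, 15 fell and 6 were not called (2 and 18 adjusted over the list alone), with Trib3 and Mthfd2 at -2.53 and -2.01. For ATF4 targets, camera gave adjusted p = 2.62e-06, and adjusted p = 0.709 with an estimated correlation. Among unfolded protein response genes, of 20 tested, 0 rose, 6 fell and 14 were not called (0 and 5 adjusted over the list alone), with Hyou1 at -1.56. For the unfolded protein response, camera gave adjusted p = 0.00184, and adjusted p = 0.852 with an estimated correlation. That list lost its call without Osr2 day 3 replicate 2 (camera adjusted p = 0.244). Among epithelial junction genes, of 31 tested, 18 rose, 1 fell and 12 were not called (18 and 2 adjusted over the list alone), with Tjp3, Ddr1 and Dsg2 at 1.82, 1.66 and 1.51. For junction genes, camera gave adjusted p = 0.0166, and adjusted p = 0.709 with an estimated correlation. Among cholesterol biosynthesis genes, of 23 tested, 14 rose, 0 fell and 9 were not called (14 and 0 adjusted over the list alone), with Hmgcs1 at 1.11. For cholesterol genes, camera gave adjusted p = 0.0166, and adjusted p = 0.852 with an estimated correlation. Among interferon-stimulated genes, of 15 tested, 9 rose, 0 fell and 6 were not called (10 and 0 adjusted over the list alone), with Ifit3 at 2.58. For interferon-stimulated genes, camera gave adjusted p = 0.0186, and adjusted p = 0.709 with an estimated correlation. Fn1 rose by 2.30 while S100a4 was at -1.33. Fibroblast markers, the check for another cell type, were not called as a list, with a median log2 fold change of 1.78 over 6 tested.

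With median-of-ratios scaling the split of 64.7% higher became 3007 higher and 2578 lower (53.8%), and with quantile normalization 2624 and 2797 (48.4%), with shifts of the median of all genes of -0.10 and -0.18, and the uncalled mesenchymal and collagen lists changed the sign of their median with quantile normalization. Without Osr2 day 9 replicate 1 or 2 the comparison called 2856 and 2605 genes, 2284 were called without any 1 of the 4 libraries, and without Osr2 day 3 replicate 1 the junction and cholesterol lists lost their call (camera adjusted p = 0.0859 and 0.175), as did the interferon list.

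Osr2 day 9 was also compared with TGF-β directly. The 2 groups also differ in days and in the vector, so this comparison does not separate Osr2 from TGF-β. The cytokine gene Il11 was lower with Osr2, at 0.433 ± 0.00429 against 136 ± 33.4 TPM (SD, n = 2; log2 fold change -6.55, adjusted p = 3.52e-05). Ctsw, Thbs1, Col7a1, Capg and Lce1g were also lower, with log2 fold changes of -5.15, -4.58, -4.60, -4.66 and -4.96. Alb was higher with Osr2, at 768 ± 49.3 against 6.06 ± 6.57 TPM, with 171 in the control, as were Osr2, Pdzk1ip1 (5.92), Sult1a1 (5.90) and Cyp4a12a (5.74). Fxyd3 had 290 reads with Osr2 and 3 with TGF-β.

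Of 3727 genes called between Osr2 day 9 and TGF-β, 1554 were higher with Osr2 and 2173 lower. Among SMAD targets, of 25 tested, 3 rose, 17 fell and 5 were not called (3 and 17 adjusted over the list alone). For SMAD targets, camera gave adjusted p = 9.74e-05, and adjusted p = 0.465 with an estimated correlation. Among BMP and ID targets, of 11 tested, 9 rose, 1 fell and 1 was not called (9 and 1 adjusted over the list alone), with Atoh8, Id3 and Bmp4 at 4.12, 3.18 and 2.42. For BMP and ID targets, camera gave adjusted p = 5.57e-05, and adjusted p = 0.465 with an estimated correlation. Among p53 targets, of 20 tested, 11 rose, 0 fell and 9 were not called (11 and 0 adjusted over the list alone), with Btg2 at 2.82. For p53 targets, camera gave adjusted p = 5.57e-05, and adjusted p = 0.465 with an estimated correlation. Among cell cycle genes, of 30 tested, 0 rose, 21 fell and 9 were not called (0 and 25 adjusted over the list alone), with Top2a at -1.40. For cell cycle genes, camera gave adjusted p = 1.41e-05, and adjusted p = 0.563 with an estimated correlation. Among epithelial transcription factors, of 12 tested, 7 rose, 1 fell and 4 were not called (8 and 1 adjusted over the list alone), with Cebpa and Foxa1 at 1.87 and 1.65. For epithelial transcription factors, camera gave adjusted p = 0.000954, and adjusted p = 0.465 with an estimated correlation. Among mesenchymal and EMT markers, of 21 tested, 1 rose, 10 fell and 10 were not called (1 and 10 adjusted over the list alone), with Itga5 and Col5a1 at -3.05 and -2.35. For mesenchymal and EMT markers, camera gave adjusted p = 0.00424, and adjusted p = 0.549 with an estimated correlation. Among actin cytoskeleton genes, of 20 tested, 0 rose, 11 fell and 9 were not called (0 and 12 adjusted over the list alone), with Pdlim7 at -1.55. For actin genes, camera gave adjusted p = 0.000954, and adjusted p = 0.549 with an estimated correlation.

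The other lists called between Osr2 day 9 and TGF-β were immediate early, ribosomal protein, epithelial junction, histone and cholesterol genes, all higher, and Wnt targets and collagens, lower. Members that rose and fell, adjusted over the list alone in brackets, were 9 and 3 of 18 (10 and 3), 13 and 1 of 32 (13 and 2), 13 and 4 of 31 (14 and 5), 3 and 0 of 13 (3 and 0), 6 and 0 of 23 (6 and 0), 1 and 7 of 10 (1 and 7) and 2 and 13 of 25 (5 and 13). In that order the camera adjusted p values were 0.00248, 0.00248, 0.0183, 0.0215, 0.0222, 0.0222 and 0.0222, and adjusted p = 0.549, 0.563, 0.465, 0.549, 0.669, 0.465 and 0.549 with an estimated correlation. Fos and Egr1 were higher with Osr2 by 3.72 and 3.44, and the Wnt target Ccn4 was at -2.32. With median-of-ratios scaling the split of 41.7% higher became 1984 higher and 1773 lower (52.8%), and with quantile normalization 1901 and 2100 (47.5%). Without Osr2 day 9 replicate 1 or 2, or TGF-β replicate 1, the comparison called 1306, 1391 and 1869 genes, and 1081 were called without any 1 of the 4 libraries.

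The responses to Osr2 at day 9 and to TGF-β, each against the control, shared 177 genes called higher in both and 109 called lower in both, with 97 called in opposite directions. Independent lists would share 72.04, 26.0 and 86.6. Fisher's exact test on calls in either direction gave p = 7.74e-55 against independence. It takes genes as independent and leaves out the shared controls, so it is no test of a shared direction. In the fit of all 8 libraries, Fn1, Vim, Zeb2 and Timp3 rose in both, and Cdh1 and Krt19 fell in both. The day 9 calls of all these genes but Timp3 were lost when any library of that comparison was left out. Leaving out a library widens the error by construction. Ranked by the smaller of their 2 changes, the 5 largest among the opposite genes that met the naming rule were Sult1a1 (3.08 with Osr2 and -2.82 with TGF-β), Atoh8 (1.95 and -2.17), Gstm1 (1.93 and -2.60), Capg (-2.79 and 1.87) and Acsbg1 (-1.81 and 2.44). Their day 9 calls were likewise lost when any library of that comparison was left out. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.151 and covariance 0.0489, against a simulated mean of r = 0.501 and covariance 0.0264 from 100 data sets with no effect and the same controls. The sign was the same in 53.9% of genes, against 66.7% in the simulated sets. In those sets all change is noise, and the shared controls alone set r and the sign share. These 2 values are therefore no baseline for how alike real responses are. With each response set against its own control library, in both possible ways and chosen after the data had been seen, the covariance was 0.0243 and 0.0283, the same sign held in 48.8% and 52.6% of genes, and 10 and 17 genes were called in the same direction. Split in this way, the controls gave r of 0.0696 and 0.0814. Each response then had 1 control library, so fewer calls were expected, and part of the 286 shared calls may come from the shared controls. The 286 became 672 with only the 4 libraries of each comparison, 681 with library weights and 9 to 500 without 1 library.

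At Osr2 day 3 and with TGF-β, 397 genes were called higher in both, 593 lower in both and 182 in opposite directions, where independent lists would share 187.5, 184.2 and 415.8. The covariance was 0.210 against a simulated 0.0263, with r = 0.474 against 0.501 and the same sign in 63.1% of genes against 66.7%. The simulated r and sign share are no baseline here either, and r was 0.386 and 0.419 with the controls split. With the controls split, the covariance was 0.182 and 0.193, and 286 and 271 genes were called in the same direction, against 284 to 1281 without 1 library. Osr2 day 3 and day 9 shared 167 higher and 216 lower genes, with 99 opposite, against 71.0, 67.2 and 155.7 for independent lists. Over all 12343 genes, 48.5% had the same sign against 66.6% in the simulated sets, with r = 0.210 against 0.499 and covariance 0.0711 against 0.0263 (0.0449 and 0.0520 with the controls split). Again the simulated r and sign share are no baseline, and r was 0.123 and 0.145 with the controls split. The 383 genes called in the same direction became 27 and 14 with the controls split, 15 to 534 without 1 library, 724 with only the 4 libraries of each comparison and 652 with library weights. Aqp8, Mmp13, Timp3, Vim and Zeb2 rose at both Osr2 times, and Muc1, Krt19, Ocln and Cdh1 fell at both. The day 9 calls of Vim, Zeb2, Krt19, Ocln and Cdh1 were lost when any library of that comparison was left out.

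**Figure D3:**
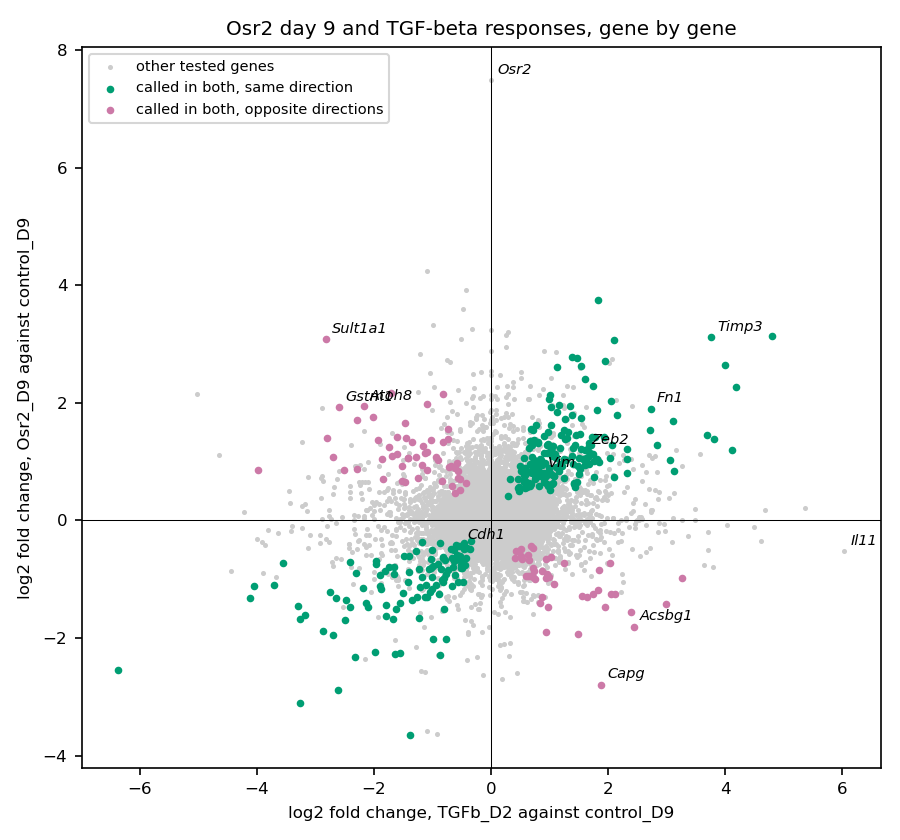
Log2 fold change of each tested gene at Osr2 day 9 and with TGF-β, both against the same control libraries, with genes called in both comparisons colored by whether the directions matched. Il11 rose with TGF-β and not with Osr2 at day 9, while Fn1, Vim and Zeb2 rose with both.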

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

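The tests of causes in this part were all chosen after the results had been seen. Against the same control, 99 genes were called one way at Osr2 day 3 and the other way at Osr2 day 9, with the difference between the times itself called. Days in culture are not separated from Osr2 in the day 3 values. These were flagged because the 2 time points differed. Of them, 29 were higher at day 3 and lower at day 9, and 70 the reverse. Ranked by the smaller of their 2 log2 fold changes against the control, the first 5 that met the filters of the naming rule, with their day 9 minus day 3 log2 fold changes, were the proliferin Prl2c2 (-6.48, with 501 TPM at day 3, 3.95 at day 9 and 60.6 in the control), the sulfotransferase Sult1a1 (5.68, with 0.639, 76.2 and 8.15 TPM), Mir1839 (4.39, with 0 reads at day 3 and 14 at day 9), Nkain4 (3.32) and Tigit (-4.16). Prl2c2 and Sult1a1 belong to families that share reads, and Mir1839 is a small RNA, so their reads are uncertain.

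The first pattern weighed was that 990 genes, 397 higher and 593 lower, were called in the same direction at Osr2 day 3 and with TGF-β. A lasting response to Osr2 predicted that these genes keep their change at day 9. Their median signed log2 fold change was 0.95 at day 3 and 0.13 at day 9 (0.11 to 0.14 without 1 library), which did not match that prediction. The genes were picked by their day 3 calls, which by itself raises the day 3 value. How much it does so was not tested. At day 9, 17.3% were called the same way, 171 of 990, but few genes were called in that comparison, and with no control at day 3 days in culture and an early, passing effect of Osr2 cannot be told apart. The controls used by both comparisons would give shared changes of their own, but the covariance exceeded that of simulated data by 0.184, above every simulated set, and was 0.182 and 0.193 with each response against its own control library.

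The second pattern was that plasma protein genes of the liver type, a list of 20 chosen after the results had been seen, were lower at Osr2 day 3 and with TGF-β than in both day 9 groups. At day 3, 0 rose and 16 fell (0 and 17 adjusted over the list alone), with a median of -2.48, and with TGF-β 0 rose and 18 fell (0 and 18), with a median of -2.40. Camera gave p = 2.20e-07 and 1.63e-16, and p = 0.136 and 0.0414 with an estimated correlation, not adjusted for the choice of list. Repression by Osr2 predicted that they stay low at day 9, but their median against the control was 0.23, with 1 higher and 2 lower. Of the 20, 9 had a log2 fold change below 0 in that comparison. The median speaks for the list as a whole and leaves repression of single members open. Liver RNA from 1 source outside the culture, if it alone gave these reads, predicted 1 ratio of Alb to Ttr in both day 9 groups, within 2-fold. The ratio was 26.5 times as high with Osr2 as in the control. A change in Alb or Ttr made by the cells themselves would also move the ratio, so it cannot exclude some outside RNA. Days in culture were not tested for this list.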

How the results depend on the processing

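The alternatives below include voom, library weights and split controls, chosen after the data had been seen. Pseudocounts, scaling, rescaling without Osr2, voom, both eBayes settings and a filter of TPM 5 kept every total of called genes and of genes shared in the same direction within 1.5 times its value. By direction, voom moved the 342 lower genes of Osr2 day 9 to 521 and the 109 lower in both Osr2 day 9 and TGF-β to 188. With the replicate number as a block the comparisons called 3976, 836, 2413, 5276 and 3690 genes (Osr2 day 3, Osr2 day 9 and TGF-β against the control, then Osr2 day 9 against Osr2 day 3 and against TGF-β).

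A minimum log2 fold change of 1 by construction left 1186, 469, 971, 1822 and 1405 genes in the same order, and overlaps in the same direction of 118 (Osr2 day 9 and TGF-β), 153 (Osr2 day 3 and day 9) and 311 (Osr2 day 3 and TGF-β). For Osr2 day 9 against the control, a fit of only the 4 libraries compared called 3304 genes and library weights called 2804, with overlaps of 672 and 681 with TGF-β and of 724 and 652 with Osr2 day 3, and with no filter 178 genes overlapped with TGF-β. The spread shared by the groups came largely from the Osr2 day 3 and TGF-β pairs, whose replicate differences had SDs of 0.443 and 0.437 against 0.285 in Osr2 day 9 and 0.301 in the control. The cause of the change without a filter was not tested.

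Leaving out 1 library gave 1633 to 4351 genes for Osr2 day 3, 25 to 1385 for Osr2 day 9 and 754 to 3279 for TGF-β, each against the control, 2605 to 5557 for Osr2 day 9 against day 3 and 1306 to 4558 for Osr2 day 9 against TGF-β. The overlaps ranged from 9 to 500 (Osr2 day 9 and TGF-β), 15 to 534 (Osr2 day 3 and day 9) and 284 to 1281 (Osr2 day 3 and TGF-β). With each response against its own control library they were 10 and 17, 27 and 14, and 286 and 271 in the same order. Where a group was left with 1 library, that lone sample is assumed to vary like the other groups. Fewer libraries widen the error by construction, while leaving out either library of the Osr2 day 3 or TGF-β pair raised the counts of comparisons without that group, as with Osr2 day 3 replicate 1 or 2 for Osr2 day 9 (1382 and 1385) and for TGF-β (3273 and 3279), and TGF-β replicate 1 or 2 for Osr2 day 3 (4335 and 4351).

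Reversals of direction were looked for only among the EMT and TGF-β genes, the called genes that the naming rule picked and the called lists. Those found were all in genes not called with all 8 libraries. Zeb1 at Osr2 day 3 was at 0.0570 with median-of-ratios scaling, 0.19 with quantile normalization, 0.0113 with voom and -0.10 to 0.0752 without 1 library, and Smad7 at Osr2 day 9 was at -0.000429 with quantile normalization and -0.11 to 0.20 without 1 library. Without 1 library, Zeb1 at Osr2 day 9 ranged from -0.11 to 0.0643, Cdh2 at Osr2 day 3 from -0.19 to 0.23, Smad7 at Osr2 day 3 from -0.13 to 0.17, and Fn1 at Osr2 day 3 from -1.31 to 0.52. The highest Fn1 value, without Osr2 day 3 replicate 2, was called (adjusted p = 0.0172). The cause was not tested.

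Of the 68 list calls, 67 were kept with the replicate block, 65 with median-of-ratios scaling, 60 with quantile normalization, 59 with a filter of TPM 5 and 44 with fry, and 0 with an estimated correlation. The fibroblast list at Osr2 day 9 lost its call in 6 settings (adjusted p 0.0585 to 0.115), the protease list at Osr2 day 3 in 5, and the p53 and Wnt lists at Osr2 day 3 in 12 and 11. Without control replicate 1, 5 of the 15 list calls at Osr2 day 9 were lost. For Osr2 day 9 against TGF-β, the mesenchymal list lost its call without TGF-β replicate 1 or 2 (0.0509 to 0.0687), collagens in 4 settings (0.0553 to 0.492), histones in 3 (0.0614 to 0.0936), Wnt targets in 2 (0.238 to 0.465), ribosomal proteins with quantile normalization (0.0804) and cholesterol genes without TGF-β replicate 2 (0.624). At Osr2 day 9 against the control, interferon genes lost their call in 3 settings (0.0510 to 0.0817), NF-kB genes, Notch targets, ATF4 targets and collagens in 2 each, and mesenchymal markers with a filter of TPM 5. With TGF-β, calls were lost for NF-kB genes in 3 settings, fatty acid synthesis in 2, and the NRF2, Wnt, YAP and cell cycle lists in 1 each. The eBayes settings do not enter camera and gave no list values.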

Other observations

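The lists and tests in this part were chosen after the results had been seen. The uroplakin Upk1b, a membrane protein of bladder epithelium, rose at Osr2 day 3 and day 9 to 47.0 ± 30.9 and 97.1 ± 6.93 TPM from 8.83 ± 1.95 (SD, n = 2), and Upk3b rose at day 9 to 11.9 ± 1.24 from 0.372 ± 0.110 TPM. Of 3 uroplakin genes tested, 1 was higher and 2 were not called at Osr2 day 3, and 2 were higher and 1 was not called at day 9. The day 9 call of Upk1b was lost when any library of that comparison was left out. With TGF-β, Upk1b was at -0.99 and was not called. Among 18 FOXO target genes, 1 rose and 9 fell at Osr2 day 3 (3 and 9 adjusted over the list alone), and 11 rose and 0 fell from Osr2 day 3 to day 9. Against the control, 2 rose and 1 fell at Osr2 day 9, and 4 rose and 2 fell with TGF-β. Txnip, an inhibitor of glucose uptake, fell from 147 ± 0.667 to 25.6 ± 9.72 TPM at day 3 and stood at 149.9 ± 8.88 at day 9. Pik3ip1, an inhibitor of PI3 kinase, fell at day 3 by 1.09 and rose at day 9 by 2.77 on the log2 scale.

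Among 14 heat shock genes, 8 rose and 0 fell at Osr2 day 3 (9 and 0 adjusted over the list alone), with the chaperone Hsph1 at 189.6 ± 116 TPM against 67.6 ± 2.40. In the day 3 pair, 12 of the 14 were higher in replicate 2, with a median difference of 0.64.

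The third pattern weighed was that the 2 Osr2 day 3 libraries differed in Osr2 and in many other genes. For counting noise, chi-square per degree of freedom was 60.5 among the genes with the most reads. Over all genes it was 21.9, against 17.1 between the TGF-β, 4.06 between the control and 1.95 between the Osr2 day 9 libraries. These values argue against counting noise alone for the day 3 pair. They do not say what else differed, since the libraries may come from separate samples. A dose effect of Osr2 predicted that genes called at day 9 lie further in their day 9 direction in the library with more Osr2. Their median difference was 0.15, against -0.11 between the TGF-β libraries, which carried no Osr2, so a dose effect and other differences between the 2 libraries cannot be told apart.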
